A study of Homo sapiens with 29 samples.

How the data were processed

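HuES6 human embryonic stem cells kept in a chemically defined medium were replated on Matrigel and differentiated in a medium without serum or albumin. Per the labels, FGF2 was given at 10 ng/ml, BMP4 at 1 ng/ml and a WNT-activating compound named there CHIR00921 at 1 uM on day 0, and the WNT inhibitor IWP-2 at 2 uM on days 2 and 3. Insulin was withdrawn from day 1. The protocol text is the same for every sample, and which factor an arm lacked was taken from each sample's own description. Total RNA was column purified with DNase treatment, amplified with a 14 h transcription step, labelled with biotin and hybridised to Illumina bead arrays, per the labels. There was 1 array for day 0 and 1 array for each of 4 arms on each of 7 days, 29 in all.

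The deposited raw table holds each probe's mean bead signal, an intensity on a linear scale with the background included, summarised in GenomeStudio per the submitters' processing notes. Its version is not given in the sources used here. A detection p-value stands beside each signal in the deposited table. These p-values move in steps of 1 in 770, which is the number of negative controls they were computed from. The authors' processed table holds intensities with negative values down to -13.0, and all 29 columns have a median of 6.88. Background subtraction and a normalisation between arrays are seen in those values, but their method is not given in the sources used here. The log2 of the authors' values and of the raw signal correlated at r of 0.995 or more on each array, across the brighter probes. Only probes well above the authors' median entered, so this does not cover dim signals. Raw medians lay between 94.8 and 110.05, and between 34.3% and 39.7% of the 47323 probes were detected per array at a detection p under 0.01. The number of arrays limits the precision.

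Raw signals were background corrected, quantile normalised and taken to log2 with limma's neqc (limma 3.58.1, R 4.3.3; offset 16), with the negative controls inferred from the detection p. Gene names came from the platform annotation, which gives 1 symbol for 30113 probes, several for 8 and none for 17202. Probes with several symbols or none were left out of the gene results. Each of 20046 genes was represented by its probe with the highest mean over the 29 arrays, and 6691 genes had more than 1 probe. Among the named comparisons, 116 had another detected probe, and 0 of these had a probe going the other way by 0.5 log2. This rule does not count smaller changes of sign and does not ask for a like size. In FW on days 4 to 8 another probe of MYL4 gave -2.66 against -7.00, while for PDGFRA it gave -6.04 against -6.10. For NANOG on day 8 against day 1 it gave -1.91 against -5.30. A gene was tested where its probe was detected on at least 3 arrays of the fit.

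Arms were compared by limma (lmFit, then eBayes with a trend) with day as a block, in the window of days 1 to 3 (12 arrays, 6 residual degrees of freedom) and that of days 4 to 8 (16 arrays, 9 residual degrees of freedom). All 4 arms entered each fit and shared the estimate of the spread. FB, BW and FW were each set against the same FBW arrays, so their differences share the chance values of FBW. An F test asked for any arm difference, and day 8 was compared with day 1 with arm as a block. Calls were made at a Benjamini-Hochberg adjusted p of 0.05. With 1 time course per arm, the p-values between arms measure the steadiness of a difference over days. They are too small to the degree that neighbouring days are related. Those of day 8 against day 1 set the change against the departure of the 4 arms from a common course. That spread includes the different treatments of the arms and is not variation between repeats. The FBW course against day 0 has no test, and its genes were counted at 4-fold where detected on at least 1 of both arrays. The place of a list's median was read among 10000 random lists of the same size matched on mean expression.

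The 19 gene lists hold 400 genes, of which 374 have a probe. They are pluripotency, primitive streak, presomitic and paraxial mesoderm, cardiac mesoderm and progenitors, cardiomyocyte contraction, definitive endoderm and liver, neuroectoderm, amnion, trophoblast and surface ectoderm, caudal HOX and CDX, BMP response, WNT response, FGF and ERK response, endothelium and blood, smooth muscle, fibroblast and epicardium, skeletal muscle, epithelial to mesenchymal transition, proliferation, p53 and stress response, and sterol synthesis. Each was tested in 7 contrasts with limma's camera at a preset correlation of 0.01, which gave 60 calls among 133 comparisons after adjustment over all of them. With a correlation estimated from the residuals 2 calls held, those of cardiac mesoderm and progenitors in FB and in FW on days 4 to 8. The median, the mean and the test of a list differed in sign in 13 comparisons, 0 of them called. Some genes belong to several lists, so the calls of such lists are not independent. TBXT and SP5 are in the primitive streak and WNT response lists, and MESP1 is in the streak and cardiac mesoderm lists. CDX1 is in the WNT response list and the caudal HOX and CDX list.

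Except for FB against FW and its alternatives, the lists, comparisons, alternatives and rule for named genes were fixed before the data were examined. The rule takes the 6 largest rises and the 6 largest falls past the threshold that had the same sign on each day and were detected on each array of the higher arm, and up to 4 members of each list with the largest difference. For the FBW course it takes the largest rises and falls on day 8 and up to 4 members of each list with the largest range. The text describes part of the genes so taken. Where a gene was not above background on any array of the dimmer arm, the difference is given as a bound, and where it was detected on some of them their number is given. The mean of the brighter arm was then set against, per array, the higher of the dim signal and the lowest signal among detected probes. Values of a named gene on single days are given without a test.

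The fits were tested on simulated data before use. For FB against FBW in days 1 to 3, over 11514 genes, 65 of 100 genes changed 2-fold and 91 of 100 changed 4-fold were recovered, with 3 false calls. In days 4 to 8, over 12060 genes, these were 83, 99 and 12. Of 50 unchanged lists 0 were called in each window. The simulated noise was independent between genes and arrays, the effects were constant over days, and the changed genes were taken from the brighter ones. These rates therefore do not cover related days, effects that grow over days, dim genes or lists whose genes vary together. The alternatives were quantile normalisation of log2 signals with an offset of 16 and no background correction, the authors' processed values, other filters on dim probes, the mean of a gene's probes or each probe by itself, array weights, no trend, no block, a fit of only the arms compared, and leaving out each day or arm in turn. Array position was not given in the tables used here, so it was not used as a block.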

Results

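Gene expression was measured with Illumina bead arrays in HuES6 cells, an established human embryonic stem cell line, during differentiation toward heart muscle. One array was made from undifferentiated cells on day 0, and 28 arrays came from 4 induction arms sampled on days 1, 2, 3, 4, 5, 6 and 8. The FBW arm received FGF2, BMP4 and a WNT-activating compound on day 0. The FB arm lacked the WNT activator, the BW arm lacked FGF2 and the FW arm lacked BMP4. Per the labels, the WNT inhibitor IWP-2 was added on days 2 and 3. Each arm and day had 1 array, so a test between arms treats the days of a window as its repeats and measures how steady a difference was over time. It does not measure variation between separate differentiations, and neighbouring days are related. The arrays detected between 16218 and 18796 of 47323 probes at a detection p under 0.01, and their number limits the precision. Values below are normalised log2 signals unless a fold is given. The FBW arrays of days 3 and 6 are described in the labels as shared with another series, and the labels used here do not say whether they came from the same differentiation as the other days. FBW is the reference of each arm comparison. Without day 3 the early counts below were 0 for FB and FW and 1 for BW, and without day 6 the late counts were 4781, 5282 and 1216.

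The first comparison asked what the full induction did over time. In the FBW arm, whose gene lists are described over the members detected on at least 1 of its arrays or on day 0, transcripts of the primitive streak, the structure from which mesoderm arises, were high on days 1 and 2. TBXT, a streak transcription factor, went from 4.82 on day 0 to 11.67 on day 1 and 12.31 on day 2 and was not above background from day 4 on. EOMES followed the same order with 6.57, 11.68 and 12.42. MESP1, a marker of early cardiac mesoderm, was 5.19 on day 0 and highest on day 2 at 12.21. The presomitic transcripts DLL3 and RSPO3 also had a day 2 high, at 13.50 and 11.46, and RSPO3 was 6.46 on day 3 and 12.43 on day 8. The median of the primitive streak list stood 3.86 log2 units above day 0 on day 2 and -0.13 from it on day 8. The presomitic and paraxial mesoderm list had a median of 2.42 on day 2 and 0.05 on day 8.

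Heart transcripts of the FBW arm followed. HAND1, a transcription factor of cardiac mesoderm, went from below background on day 0 to 12.12 on day 2 and 13.70 on day 3. PDGFRA, a receptor on cardiac mesoderm, was 10.32 on day 2 and 12.63 on day 4. NKX2-5, a cardiac transcription factor, was 5.87 on day 4, 10.02 on day 5 and 12.10 on day 8, at least 144-fold above day 0. MYH6, which encodes atrial myosin heavy chain, was 9.15 on day 4, 13.88 on day 5 and 14.01 on day 8, at least 543-fold above day 0. Its sequence is close to that of MYH7, so its probe may report both. MYL4 and MYL7, atrial myosin light chains, reached 13.94 and 13.77 on day 8. The cardiomyocyte contraction list had 37 members with a probe, of which 33 were detected on day 0 or in FBW. All 33 were at least 2-fold higher on day 8 than on day 0, and their median difference was 4.19. Of 27 cardiac mesoderm and progenitor genes, 21 were at least 2-fold higher on day 8, with a median of 3.47. Both medians lay above all 10000 random lists of the same size and mean expression.

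Members of other lists also had higher signals on day 8 than on day 0, which bulk arrays do not assign to separate cells. The median of the endothelium and blood list was 1.94 on day 8, with CD34, an endothelial and blood progenitor marker, at 8.99 on day 5 and CDH5, an endothelial cadherin, at 8.65 on day 8. COL3A1, a fibrillar collagen, went from background on day 3 to 13.00 on day 6, and ACTA2, smooth muscle actin, from 6.30 on day 0 to 13.36 on day 8. The smooth muscle, fibroblast and epicardium list had a median of 3.46 on day 6 and 1.58 on day 8. The amnion, trophoblast and surface ectoderm list had a median of 1.91 over 14 members, with IGFBP3 at 10.27 on day 8, and one of 0.75 over the 20 members detected on at least 3 of the 29 arrays. The BMP response list stood at 2.07, with SMAD6, a feedback inhibitor of BMP signalling, at 10.92 on day 8 after 6.65 on day 0. The medians 1.94, 1.58, 1.91 and 2.07 each lay above all 10000 random lists. The WNT response list had a median of 1.49 on day 1 and -0.06 on day 8. SP5, a WNT target, was 10.58 on day 1 and 4.81 on day 8. The FGF and ERK response list was 0.55 on day 2 and -0.82 on day 8.

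Signals of the pluripotency transcripts were lower on later days of the FBW arm. SOX2 was 12.02 on day 0, 7.92 on day 1 and not above background on later days, except for 5.10 on day 4. NANOG, a core pluripotency factor, was 10.24 on day 1 and 6.53 on day 2, and POU5F1, another, was 10.56 on day 2 and 5.40 on day 5. On day 8 these were lower than on day 0 by at least 128-fold for SOX2, 40.3-fold for NANOG and 88.7-fold for POU5F1. Of 24 pluripotency genes 21 were at least 2-fold lower on day 8, and the list median was -3.93, below all 10000 random lists. The proliferation list had a median of -0.38 on day 4 and -2.47 on day 8, with AURKB, a mitotic kinase, at 10.08 on day 0 and 6.17 on day 8. The neuroectoderm list had a median of -1.19 on day 8 over 11 members, and one of -0.23 over the 16 members detected on at least 3 of the 29 arrays. The sterol synthesis list had a median of 0.97 on day 1 and 0.20 on day 8. Medians on day 8 were 0.14 for the definitive endoderm and liver list, 0.29 for the caudal HOX and CDX list (0.47 over the 10 members detected on at least 3 of the 29 arrays), 0.14 for the epithelial to mesenchymal transition list (0.28 over 11 members so detected), 0.43 for the p53 and stress response list and -0.20 for 3 skeletal muscle genes (-1.10 for the 2 so detected). Each of these lists lay farther from day 0 on another day, with 0.995 for endoderm and liver and 0.86 for caudal HOX and CDX on day 6, 0.745 for epithelial to mesenchymal transition on day 2, and -0.60 for p53 and stress response and 0.55 for skeletal muscle on day 3. Genes at least 4-fold from day 0 numbered 116 on day 1, 514 on day 3, 696 on day 5 and 1067 on day 8, of which 576 were higher and 491 lower. With 1 array per day these differences have no replicate check and no test. Quantile normalisation without background correction, which compresses dim signals, gave 366 genes on day 8, and asking for detection on both arrays gave 679.

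**Figure D1:**
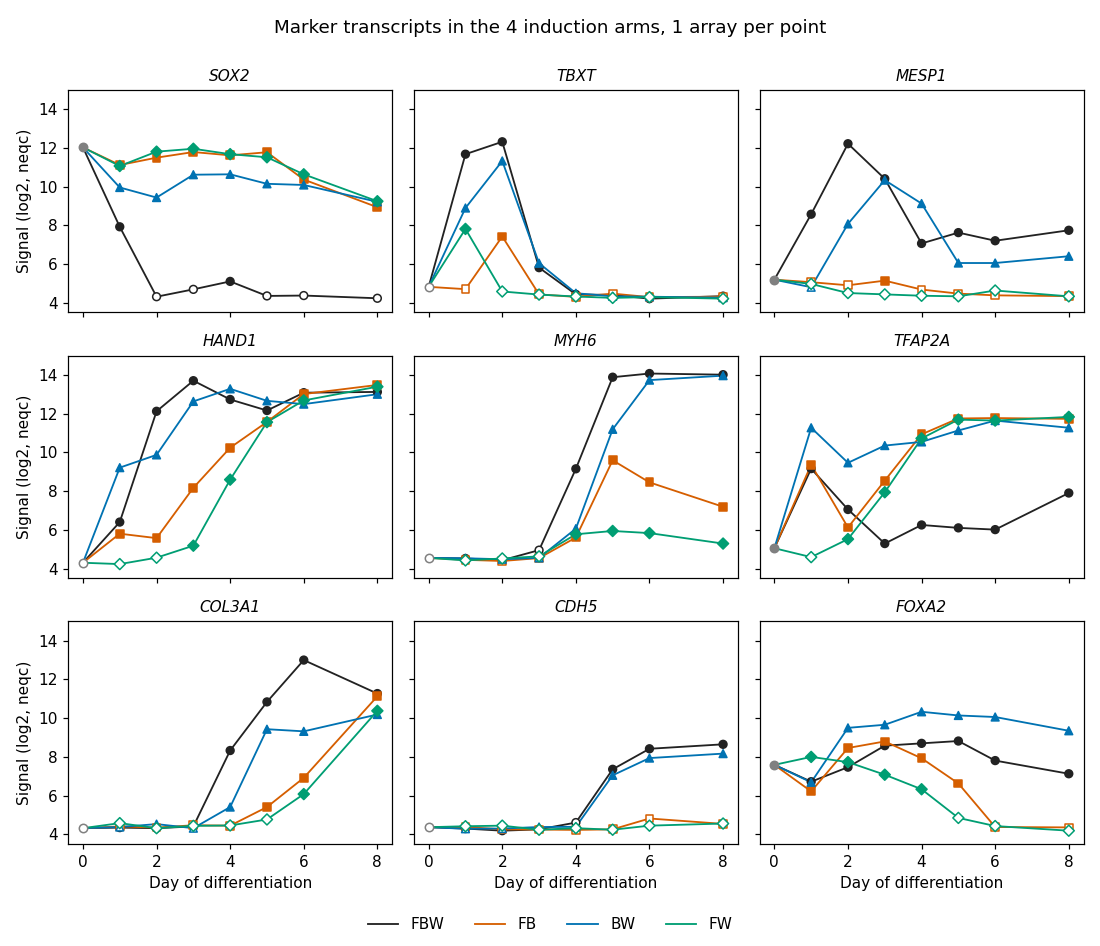
Normalised log2 signal (vertical axes) of 9 marker transcripts against the day of differentiation (horizontal axes) in the FBW, FB, BW and FW arms, 1 array per point, with the shared day 0 array in grey. Filled symbols were detected at p under 0.01 and open symbols were not; SOX2 lost detection in FBW on day 2 (4.31) and was still 9.21 on day 8 in BW.

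Leaving out the WNT activator, the FB arm of days 1 to 3 was higher than FBW in the pluripotency transcripts SOX2 and PRDM14 and lower in transcripts that include targets of WNT and BMP signalling. SOX2 was higher by 5.82 ± 0.76 (SE, n = 3 days, adjusted p = 0.0330) and PRDM14, a pluripotency regulator, by 2.99 ± 0.31 (adjusted p = 0.0143), on every day. ADM, TENT5B, LINGO1 and CPM were also higher, by 3.36 ± 0.52, 2.92 ± 0.43, 2.62 ± 0.35 and 1.87 ± 0.28. The WNT target LEF1 was lower, at -4.49 ± 0.54 (adjusted p = 0.0267), as were WLS, a carrier of WNT proteins, at -3.50 ± 0.34, and the BMP target MSX1 at -5.63 ± 0.61. WNT8A, a streak WNT ligand, was not above background in FB and at least 6.24-fold higher in FBW (adjusted p = 0.0433). CNTFR and CD1D were lower as well, at -4.23 ± 0.59 and -2.80 ± 0.37. MESP1 and MIXL1 differed by -5.36 ± 1.04 and -4.91 ± 1.00 and missed the threshold (adjusted p = 0.0617 for each). In FB, LEF1, MESP1 and MIXL1 were detected on 1 of the 3 days and MSX1 on 2, and in FBW SOX2 was detected on 1 and CPM on 2, so the other days enter at background level.

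By list, 2 of 23 tested pluripotency genes were higher in FB in these days, or 15 when adjusted over the list alone, and camera called the list higher (adjusted p = 1.11e-06, but adjusted p = 0.349 with an estimated correlation). Of 17 streak genes 1 was lower, or 11 with 1 higher when adjusted over the list alone (adjusted p = 2.53e-06, and 0.349 as the adjusted p with an estimated correlation). None of 18 cardiac mesoderm and progenitor genes passed over all genes, 9 were lower when adjusted over the list alone, and the list was called lower (adjusted p = 2.87e-06, and adjusted p = 0.349 with an estimated correlation). The WNT response list had 1 of 18 lower, 7 when adjusted over the list alone (adjusted p = 0.000244, and adjusted p = 0.349 with an estimated correlation). The BMP response list had MSX1 lower among 15 (adjusted p = 0.00234, and adjusted p = 0.349 with an estimated correlation). The caudal HOX and CDX list and the presomitic list were also called lower (adjusted p = 0.00151 and 0.0195), with adjusted p = 0.281 and 0.484 under an estimated correlation. In all 28 of 11514 genes passed, 12 higher and 16 lower, and 3247 had an unadjusted p under 0.05. Without day 1 the count was 2757, without day 2 or without day 3 it was 0, with array weights 3648 and in a fit of only the 2 arms 1. Quantile normalisation gave 6 genes, 3 of them higher, and ended the calls of ADM, TENT5B, LINGO1, CPM, MSX1, LEF1, CNTFR, WNT8A and CD1D.

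Without BMP4, the FW arm of days 1 to 3 was lower than FBW in MESP1 and HAND1, 2 of 18 cardiac mesoderm and progenitor genes tested, a list whose call had adjusted p = 0.349 with an estimated correlation. MESP1 was not above background on any of these days and at least 40.8-fold higher in FBW (adjusted p = 0.0484). HAND1 differed by -6.08 ± 1.07 (SE, n = 3 days, adjusted p = 0.0484) and the BMP target MSX1 by -5.63 ± 0.61 (adjusted p = 0.0122). MSX2, another BMP target, was at least 2.88-fold higher in FBW and LEF1 at least 22.2-fold. CNTFR differed by -4.33 ± 0.59 and HAS2, a hyaluronan synthase, by -4.01 ± 0.68. SOX2 was higher in FW by 5.96 ± 0.76 (adjusted p = 0.0304), PRDM14 by 2.82 ± 0.31 and USP44 by 2.53 ± 0.40. ADM, TENT5B and BNC2 were higher by 3.24 ± 0.52, 3.15 ± 0.43 and 2.71 ± 0.51. APLNR and EOMES, streak transcripts, differed by -6.32 ± 1.36 and -4.34 ± 0.85 and missed the threshold (adjusted p = 0.0560 and 0.0532). HAND1 was detected in FW on 1 of the 3 days and MSX1, APLNR and EOMES on 2, and in FBW SOX2 was detected on 1 and BNC2 on 2. With quantile normalisation MESP1 and HAND1 missed the threshold (limma adjusted p = 0.0671 and 0.0680), as did BNC2, HAS2 and MSX2.

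The FW arm of days 1 to 3 had 5 of 23 pluripotency genes higher, or 14 when adjusted over the list alone (camera adjusted p = 1.44e-06, and adjusted p = 0.349 with an estimated correlation). Of 17 streak genes 2 were lower, or 12 with 1 higher when adjusted over the list alone (adjusted p = 1.11e-06, and adjusted p = 0.349 with an estimated correlation). Of 15 BMP response genes 2 were lower, or 8 when adjusted over the list alone (adjusted p = 4.68e-05, and adjusted p = 0.193 with an estimated correlation), and the list median was -1.52. Of 18 cardiac mesoderm and progenitor genes 2 were lower, or 13 when adjusted over the list alone (adjusted p = 2.30e-06, and adjusted p = 0.349 with an estimated correlation). The WNT response, presomitic, caudal HOX and CDX, and sterol synthesis lists were called lower with adjusted p = 0.00126, 0.00176, 0.00176 and 0.0251, and had adjusted p = 0.373, 0.380, 0.281 and 0.621 with an estimated correlation. In all 105 of 11514 genes passed, 53 higher and 52 lower, and 3401 had an unadjusted p under 0.05. Quantile normalisation gave 31 genes, 19 of them higher, array weights gave 2639 and a fit of only the 2 arms gave 2. Without day 1 the count was 2757, and without day 2 or day 3 it was 0.

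Without FGF2, the BW arm of days 1 to 3 differed from FBW in 1 gene past the threshold. This was TFAP2C, a transcription factor of trophoblast and surface ectoderm, higher by 2.58 ± 0.25 on all 3 days (SE, adjusted p = 0.0248). Values that missed the threshold were 4.35 ± 0.76 for SOX2 (adjusted p = 0.123; detected in FBW on 1 of the 3 days), 3.19 ± 1.07 for TFAP2A, a relative of TFAP2C, and -2.43 ± 0.39 for VIM, a mesenchymal filament protein. TBXT and MESP1 of the BW arm, in the plot of marker transcripts, were highest on day 2 at 11.32 and on day 3 at 10.33. Among the lists, amnion, trophoblast and surface ectoderm was called higher (1 of 15 genes, 2 when adjusted over the list alone; adjusted p = 5.45e-06, and adjusted p = 0.0709 with an estimated correlation). So were the pluripotency list (adjusted p = 2.56e-05) and the definitive endoderm and liver list (adjusted p = 0.00475), each with adjusted p = 0.349 under an estimated correlation. The presomitic, caudal HOX and CDX, and cardiac mesoderm lists were called lower, with adjusted p = 0.00146, 0.00817 and 0.0354, and adjusted p = 0.377, 0.349 and 0.639 with an estimated correlation. An unadjusted p under 0.05 was found for 1423 genes. Quantile normalisation gave 5 genes, 4 of them higher, and leaving out day 1 gave 350. Without day as a block and without day 2 the count was 0. Without day 3 and in a fit of only the 2 arms 1 gene passed, which was not TFAP2C. Over all 4 arms, 49 genes passed the test for any arm difference in days 1 to 3, and 2044 without day 1, 0 without day 2 and 1 without day 3.

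**Figure D2:**
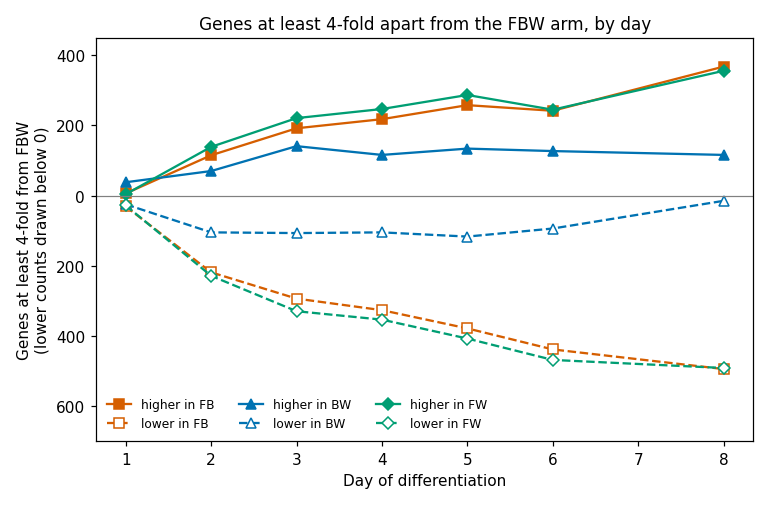
Number of genes at least 4-fold higher (solid lines, above 0) or lower (dashed lines, drawn below 0) in FB, BW or FW than in FBW on the same day (horizontal axis), 1 array per arm and day. On day 1 the FB and FW arms had 37 and 32 such genes in all and on day 8 they had 863 and 848, while BW had 63 and 131.

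From day 4 to day 8 the FB arm differed from FBW in heart, pluripotency and ectoderm transcripts. Lower cardiac mesoderm transcripts were PDGFRA by -5.90 ± 0.25 (SE, n = 4 days, adjusted p = 1.52e-08), GATA5, a cardiac transcription factor, by -4.92 ± 0.21, and the ligand BMP5 by -5.86 ± 0.40. TBX2 and HAND2, heart transcription factors, were not above background in FB and at least 32.5-fold and 10.9-fold higher in FBW. The myosin transcripts MYL4, MYL7 and MYH6 differed by -5.67 ± 0.61, -5.11 ± 0.70 and -5.07 ± 1.06, and CKM, muscle creatine kinase, was at least 14.6-fold higher in FBW. APLNR differed by -5.77 ± 0.32 and PGA5, a pepsinogen with near-identical relatives and so of uncertain identity, by -5.78 ± 0.37. Each of these passed and had the same sign on all 4 days. In FB, BMP5 was detected on 1 of the 4 days, APLNR and PGA5 on 2 and GATA5 on 3, so their differences rest in part on background values. Of 26 tested cardiac mesoderm and progenitor genes 19 were lower and 1 higher, with 21 lower when adjusted over the list alone; this list was called lower with the preset correlation (adjusted p = 5.92e-08) and with an estimated one (adjusted p = 0.0121). Of 33 contraction genes 25 were lower and 2 higher (26 and 2 adjusted over the list alone; adjusted p = 9.70e-06, and adjusted p = 0.476 with an estimated correlation).

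Pluripotency and ectoderm transcripts were among those higher in FB in the same days. SOX2, detected in FBW on day 4 alone of these days, was higher by 6.15 ± 0.33 (adjusted p = 6.86e-08) and POU5F1 by 3.28 ± 0.29. TFAP2A, TFAP2C and DLX5, transcription factors of surface ectoderm, were higher by 4.98 ± 0.29, 4.49 ± 0.23 and at least 41.6-fold. The neural transcription factors SOX21 and ZIC2 were higher by 5.04 ± 0.54 and 4.62 ± 0.53, and HESX1 by at least 10.4-fold. CYP26A1, which degrades retinoic acid, was higher by 5.63 ± 0.45, the epithelial cadherin CDH1 by 3.98 ± 0.17 and AFP, alpha-fetoprotein, by 3.74 ± 0.49. In FBW, SOX21 was detected on 1 of the 4 days and POU5F1, TFAP2C, ZIC2 and AFP on 2. Pluripotency genes were higher in 15 of 21 cases and lower in 2 (16 and 2 adjusted over the list alone; adjusted p = 6.49e-05, and adjusted p = 0.107 with an estimated correlation). For amnion, trophoblast and surface ectoderm 13 of 19 were higher and 1 lower (adjusted p = 0.00176, and adjusted p = 0.447 with an estimated correlation). Neuroectoderm had 10 of 15 higher and 1 lower (adjusted p = 0.0120, and adjusted p = 0.387 with an estimated correlation). Adjusted over the list alone, 13 genes of the former and 12 of the latter list were higher and 1 of each lower. Proliferation had 16 of 20 higher and 1 lower, also over the list alone (camera adjusted p = 0.000107, and adjusted p = 0.503 with an estimated correlation). RRM2, detected in FBW on 3 of the 4 days, was higher by 1.73 ± 0.22.

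Endothelium and blood transcripts of FB were lower in 12 of 17 cases on days 4 to 8, with CDH5 at least 4.36-fold higher in FBW (adjusted p = 0.00176, and adjusted p = 0.349 with an estimated correlation). COL3A1, detected in FB on 3 of the 4 days, differed by -3.88 ± 0.88 over the window, with 11.13 in FB and 11.27 in FBW on day 8. Without day as a block, COL3A1 missed the threshold (limma adjusted p = 0.0566). Streak genes were lower in 8 of 11 cases (camera adjusted p = 0.00876). Caudal HOX and CDX genes were lower in 6 of 7 cases, with 1 higher (camera adjusted p = 0.0214). Among the lower ones, HOXB5 (detected in FB on 3 of the 4 days) differed by -3.98 ± 0.75. With an estimated correlation the adjusted p was 0.349 for each of these lists. The counts adjusted over the list alone were 12 lower and 1 higher for endothelium and blood, 8 lower for streak, and 6 lower and 1 higher for caudal HOX and CDX genes. The lists for endoderm and liver, presomitic mesoderm, BMP, WNT and FGF response, smooth muscle and fibroblast, skeletal muscle, epithelial to mesenchymal transition, p53 and stress, and sterol synthesis were not called. Within them SMAD6 was lower by -2.67 ± 0.18, LEF1 by -3.22 ± 0.44 and SC5D, a sterol desaturase, by -2.69 ± 0.32. Of 18 endoderm and liver genes 10 were higher, AFP among them, and 4 lower, among them the transcription factor FOXA2 by -2.29 ± 0.42 (detected in FB on 2 of the 4 days), with a list median of 0.96 (adjusted p = 0.0907). In all 6510 of 12060 genes passed, 3360 higher and 3150 lower, and 851 and 1066 of them differed at least 2-fold.

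The FW arm of days 4 to 8 was lower than FBW in the heart muscle transcripts MYH6 at -7.07 ± 1.06 (SE, n = 4 days, adjusted p = 0.000146), MYL4 at -7.00 ± 0.61 and MYL7 at -6.26 ± 0.70. PDGFRA differed by -6.10 ± 0.25 and GATA5 by -5.19 ± 0.21 (adjusted p = 1.24e-08 for each). APLNR, PGA5, BMP5 and TBX2 were not above background in FW and at least 67.9-fold, 57.6-fold, 51.1-fold and 33.5-fold higher in FBW. Higher in FW were SOX2 by 6.25 ± 0.33, CYP26A1 by 5.72 ± 0.45, SOX21 by 5.34 ± 0.54, TFAP2A by 4.90 ± 0.29 and ZIC2 by 4.53 ± 0.53, and DLX5 by at least 41.1-fold. In FBW, SOX2 and SOX21 were detected on 1 of the 4 days and ZIC2 on 2, and in FW PDGFRA and GATA5 were detected on 3. Cardiac mesoderm and progenitor genes were lower in 21 of 26 cases and higher in 1, also when adjusted over the list alone, and this list was called with the preset correlation (adjusted p = 5.92e-08) and with an estimated one (adjusted p = 0.0121). Contraction genes were lower in 26 of 33 cases and higher in 1, also when adjusted over the list alone (adjusted p = 1.44e-06, and adjusted p = 0.447 with an estimated correlation). HAND1 was 13.39 in FW, 13.48 in FB, 13.00 in BW and 13.12 in FBW on day 8.

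Pluripotency genes of the FW arm were higher in 15 of 21 cases and lower in 2 (16 and 2 adjusted over the list alone; adjusted p = 4.58e-05, and adjusted p = 0.107 with an estimated correlation), among them POU5F1 (detected in FBW on 2 of the 4 days) by 3.47 ± 0.29 and ZFP42 by 3.46 ± 0.18. Amnion, trophoblast and surface ectoderm genes were higher in 13 of 19 cases, neuroectoderm genes in 10 of 15 and proliferation genes in 16 of 20, with 1 gene of each list lower. Adjusted over the list alone these were 13, 11 and 16, with 1 of each lower. Their adjusted p were 0.00687, 0.0135 and 0.000107, and with an estimated correlation adjusted p = 0.484, 0.390 and 0.503. Endothelium and blood genes were lower in 13 of 17 cases, smooth muscle, fibroblast and epicardium genes in 10 of 18, streak genes in 6 of 11 and caudal HOX and CDX genes in 6 of 7, while 2 smooth muscle, fibroblast and epicardium genes and 1 caudal HOX and CDX gene were higher. Adjusted over the list alone those lower were 13, 10, 8 and 6. Their adjusted p were 0.00129, 0.0435, 0.0124 and 0.0351, and with an estimated correlation adjusted p = 0.349, 0.503, 0.349 and 0.358. COL3A1, detected in FW on 2 of the 4 days, differed by -4.44 ± 0.88 and ACTA2 by -2.51 ± 0.30. Without day as a block, ACTA2 missed the threshold (limma adjusted p = 0.180). CDH1 was higher by 3.76 ± 0.17 and VIM lower by -2.61 ± 0.38. The remaining lists were not called in FW. In all 6983 of 12060 genes passed, 3605 higher and 3378 lower, with 921 and 1170 at least 2-fold.

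The BW arm of days 4 to 8 carried heart muscle transcripts beside ectoderm transcripts and some of the pluripotency transcripts. MYH6 was 13.96 in BW and 14.01 in FBW on day 8, after 6.06 and 9.15 on day 4; its mean difference of -1.54 ± 1.06 and that of MYL7, -1.68 ± 0.70, missed the threshold (adjusted p = 0.303 and 0.0954). SOX2 was higher by 5.50 ± 0.33 (SE, n = 4 days, adjusted p = 9.26e-07), ZIC2 by 4.61 ± 0.53, TFAP2A by 4.58 ± 0.29, GABRP, an amnion-enriched receptor subunit, by 4.04 ± 0.89, CYP26A1 by 4.66 ± 0.45 and CDH1 by 3.63 ± 0.17. DLX5 was higher by at least 13.6-fold. In FBW, SOX2 was detected on 1 of the 4 days and ZIC2 and GABRP on 2. POU5F1 was 5.46 in BW on day 8, against 7.59 in FB and 7.80 in FW. NANOG was not above background in BW on days 6 and 8, and PRDM14 was not on day 8. Higher endoderm and epithelial transcripts were FOXA2 at 1.86 ± 0.42, EPCAM, an epithelial adhesion protein, at 1.92 ± 0.08, PRDM1 at 2.08 ± 0.33 and CXCR4 at 1.40 ± 0.27. Lower were the cardiac factors TBX2 at -3.28 ± 0.27, HAND2 at -2.10 ± 0.32 and MEF2C at -1.90 ± 0.42, BMP5 at -3.12 ± 0.40, and COL22A1, SFRP5 and SLC47A1 at -3.00 ± 0.47, -2.97 ± 0.43 and -2.90 ± 0.41. NR2F1, an atrial transcription factor, was not above background in BW and at least 5.25-fold higher in FBW. HAND2, MEF2C and SLC47A1 were detected in BW on 3 of the 4 days. Without day 5, GABRP and MEF2C missed the threshold (limma adjusted p = 0.0851 and 0.0855). Without day as a block, GABRP and FOXA2 missed it (limma adjusted p = 0.101 and 0.0941).

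Of 26 cardiac mesoderm and progenitor genes 12 were lower in BW and 1 higher (13 and 1 adjusted over the list alone; adjusted p = 4.52e-05, and adjusted p = 0.0528 with an estimated correlation). Of 33 contraction genes 5 were lower and 1 higher, also over the list alone (adjusted p = 0.00131, and adjusted p = 0.639 with an estimated correlation). Pluripotency genes were higher in 11 of 21 cases and lower in 2 (14 and 2 adjusted over the list alone; adjusted p = 5.45e-06, and adjusted p = 0.0709 with an estimated correlation). Endoderm and liver genes were higher in 8 of 18 cases (12, with 1 lower, adjusted over the list alone; adjusted p = 3.06e-05, and adjusted p = 0.0587 with an estimated correlation) and amnion, trophoblast and surface ectoderm genes in 9 of 19 (11, with 1 lower, adjusted over the list alone; adjusted p = 9.70e-06, and adjusted p = 0.349 with an estimated correlation). Proliferation genes were higher in 8 of 20 cases, FGF and ERK response genes in 8 of 17 and neuroectoderm genes in 5 of 15 with 1 lower, and caudal HOX and CDX genes were lower in 4 of 7. Adjusted over the list alone these were 10, 9, 7 and 6. Their adjusted p were 2.02e-05, 0.000643, 0.0331 and 0.00176, and with an estimated correlation adjusted p = 0.474, 0.377, 0.468 and 0.291. The endothelium and blood list was not called, with CDH5 at 8.17 in BW and 8.65 in FBW on day 8. In all 3098 of 12060 genes passed, 1594 higher and 1504 lower, with 396 and 267 at least 2-fold. The count was 1477 without day as a block, 1166 without day 5 and 1216 without day 6. The test for any arm difference in days 4 to 8 passed for 6639 genes, 4312 without day 5 and 4181 without day 6.

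**Figure D3:**
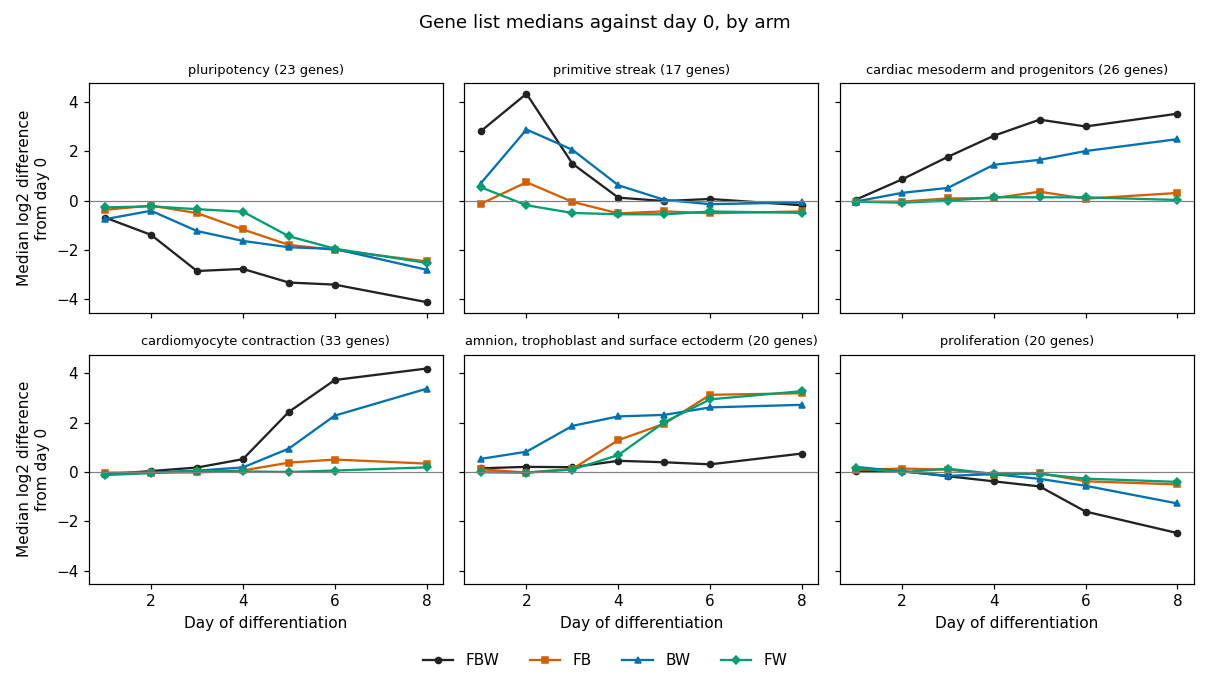
Median log2 difference from the day 0 array (vertical axes) of 6 gene lists against the day of differentiation (horizontal axes) in each arm, over the list members detected on at least 3 of the 29 arrays, 1 array per point. The cardiomyocyte contraction median of FBW and BW parted from that of FB and FW from day 5 on, and the pluripotency median was lowest in FBW on day 8.

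The FB and FW arms were also set against each other, a comparison added after the data were examined. They were at least 4-fold apart in 19 genes on day 1, 10 on day 2, 5 on day 3, and 2, 8, 3 and 7 on days 4, 5, 6 and 8. TBXT was 7.81 in FW and not above background in FB on day 1, and 7.42 in FB and not above background in FW on day 2. With limma on all 4 arms no gene passed in days 1 to 3 (296 at an unadjusted p under 0.05) or in days 4 to 8 (765 unadjusted). In a fit of these 2 arms alone 185 genes passed in days 4 to 8, 102 of them higher in FB, while array weights on all 4 arms gave 91 genes, 29 of them higher in FB. With the preset correlation, camera called the definitive endoderm and liver list higher in FB in days 4 to 8 (adjusted p = 7.06e-05). Its median was 0.43, and its adjusted p was 0.0652 with an estimated correlation. Likewise the BMP response list was called higher in FB in days 1 to 3 (camera adjusted p = 0.0210). Its median was 0.37, and with an estimated correlation its adjusted p was 0.729.

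**Figure D4:**
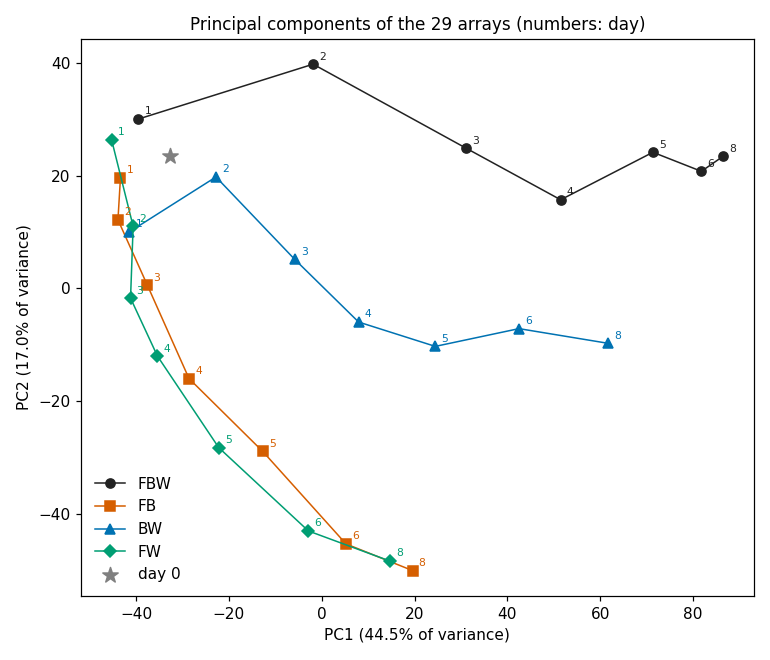
First (horizontal) and second (vertical) principal components of 12711 detected genes over the 29 arrays, with 44.5% and 17.0% of the variance; points are arrays joined by arm in order of day, numbers are days. The FB and FW arms ran side by side to values of 19.5 and 14.7 on the first component on day 8, BW reached 61.7 and FBW 86.4.

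Day 8 was also compared with day 1 as a mean over the 4 arms, whose own values are given below for several lists. The SE and p-values rest on how far the arms departed from a common course, which includes their different treatments. IGFBP5 was higher on day 8 by 7.27 ± 0.98 (SE, n = 4 arms, adjusted p = 5.14e-06), HAND1 by 6.84 ± 1.16, the imprinted RNA H19 by 6.76 ± 1.18 and ACTC1, cardiac actin, by 6.69 ± 0.80. GABRP and COL3A1 were not above background on day 1 and at least 62.0-fold and 50.2-fold higher on day 8. NANOG was lower by -5.30 ± 0.59, GAL by -5.46 ± 0.78, NTS by -4.83 ± 0.88, the metallothionein MT1G, one of a family of close copies, by -4.72 ± 0.44 and CAMKV by -4.59 ± 0.53, and EOMES was at least 25.3-fold higher on day 1. On day 1 IGFBP5 and H19 were detected in 1 of the 4 arms and HAND1 in 3, and on day 8 NANOG was detected in 1, CAMKV in 2 and GAL and MT1G in 3. In this mean, contraction genes were higher in 31 of 33 cases (32 adjusted over the list alone; adjusted p = 5.92e-08, and adjusted p = 0.377 with an estimated correlation). Their median on day 8 stood 4.19 above day 0 in FBW and 3.37 in BW, but 0.34 in FB and 0.19 in FW, after -0.09, -0.10, -0.03 and -0.12 on day 1. In the mean of the arms, pluripotency genes were lower in 21 of 23 cases (21 adjusted over the list alone; adjusted p = 2.13e-08, and adjusted p = 0.0528 with an estimated correlation). Proliferation genes were lower in 18 of 20 cases. Sterol synthesis genes were lower in 10 of 12 cases, among them CYP51A1 at -1.21 ± 0.14, with 1 other gene higher. Adjusted over the list alone those lower were 19 and 10. Their adjusted p were 1.42e-06 and 0.00271, and with an estimated correlation adjusted p = 0.380 and 0.387. WNT response genes were lower in 11 of 18 cases and higher in 1 (11 and 2 adjusted over the list alone; adjusted p = 0.0259, and adjusted p = 0.482 with an estimated correlation).

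Also higher on day 8 in the mean of the 4 arms were amnion, trophoblast and surface ectoderm genes in 13 of 20 cases, with IGFBP3 (detected on day 1 in 1 of the 4 arms) at 6.17 ± 0.68, and smooth muscle, fibroblast and epicardium genes in 12 of 18, with ACTA2 at 5.46 ± 0.41. Their adjusted p were 0.000154 and 1.69e-05, and with an estimated correlation adjusted p = 0.377 and 0.193. BMP response genes were higher in 11 of 17 cases, cardiac mesoderm and progenitor genes in 13 of 26, endothelium and blood genes in 7 of 18 and endoderm and liver genes in 8 of 19. Lower were 2 cardiac mesoderm and progenitor genes and 1 gene each of the endoderm and liver list and the amnion, trophoblast and surface ectoderm list. Adjusted over the list alone the 6 lists of this paragraph had 14, 13, 11, 13, 6 and 8 genes higher. The adjusted p of the last 4 lists were 0.000549, 0.00122, 0.00509 and 0.0382, and with an estimated correlation adjusted p = 0.107, 0.349, 0.380 and 0.349. The median of cardiac mesoderm and progenitors on day 8 against day 0 was 3.53 in FBW, 2.496 in BW, 0.31 in FB and 0.03 in FW. For FBW, BW, FB and FW in turn, such medians were 1.94, 1.91, 0.07 and 0.01 for endothelium and blood, 0.13, 1.94, 0.23 and 0.44 for endoderm and liver, and 0.75, 2.72, 3.19 and 3.27 for amnion, trophoblast and surface ectoderm. The differences between arms in this contrast were not tested. HEY1 was higher by 3.22 ± 0.57 and NKX2-5 by at least 19.8-fold. In all 6507 of 12662 genes passed, 3060 higher and 3447 lower on day 8.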

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

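The tests of a shared RNA, of differences confined to the first days, of a delay, and of the number of arrays and of day 1 were chosen after the results they bear on had been seen. So was the comparison of FB with FW. The namings of arms within days were added after the any-arm counts had been seen, with their expectation set before the namings were counted.

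The difference from FBW was itself tested between the windows of days 1 to 3 and days 4 to 8, over 12662 genes. It was not the same in the 2 windows for 1447 genes in FB, 110 in BW and 1763 in FW, at a limma adjusted p under 0.05. In FB 682 of these genes were more positive late and 765 more negative, in BW 54 and 56, and in FW 857 and 906. Among the 17202 probes without a gene name, which no comparison of genes used, 4023 were tested and 2224 passed the test for any arm difference in days 4 to 8, or 55.3%. Each arm and day had 1 array, so single arrays were rated only within the fits. Such a weight falls where an array departs from the sum of its arm and day effects. It cannot tell a poor array from an arm with a course of its own. Their weights ran from 0.278 (FBW on day 1) to 5.79 (FB on day 3) in days 1 to 3 and from 0.256 (FBW on day 4) to 2.10 (FB on day 6) in days 4 to 8.

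The first pattern is the closeness of the FB and FW arms from day 4 to day 8, where no gene passed in the fit of all arms. The same RNA hybridised under both names would make the arrays of a day exchangeable, provided that both were run alike. Over all 7 days 116 of 11576 genes differed in the real naming. Of the 64 ways to swap the names within days 1, the real one, gave as many, with 38 as the highest of the others. This count pools the first days with the later ones. In days 4 to 8 alone all 8 ways gave 0 genes, so the swaps say nothing about a shared RNA in that window. Array position was not given, so a steady difference between chips cannot be told apart from one between RNAs. That the arms may differ only in the first days stays open: up to 19 genes were at least 4-fold apart on day 1 or 2 and up to 8 on a later day, while 185 genes passed in days 4 to 8 when these 2 arms were fitted alone. The verdict on this explanation was made stricter, from fitting to open, after that count was weighed.

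The second pattern is that the BW arm held cardiac transcripts beside transcripts that stayed high in FB and FW. A mixture of FBW-type and FB-type cells would give genes that are higher and genes that are lower in FB the same share of the FB level. This holds only where the array signal is linear in transcript amount, which was not tested. On day 8 the median share was 0.360 over 368 higher genes and 0.605 over 495 lower genes. The difference was -0.24 with a bootstrap range of -0.272 to -0.213 over genes, which ended just beyond the bound fixed before the test. It was -0.37, -0.28 and -0.19 on days 4, 5 and 6, with a range of -0.259 to -0.136 on day 6. The genes were chosen on the same FB and FBW arrays that enter the share. A delayed FBW course would match BW at 1 earlier time over both sets of genes, yet at the best time the larger of their median differences was 0.58 log2 on day 4 (bootstrap range over genes 0.506 to 0.706, just above the bound of 0.5), 0.78 on day 5, 0.91 on day 6 and 0.64 on day 8, which argues against a delay alone. This test took the place of one on SOX2 and MYH6. It was extended from day 8 to each day after its day 8 value was seen. The bootstrap ranges of the mixture test and the delay test leave out the error of single arrays. A cell state of its own in the arm without FGF2, or a mixture of other cell types, may underlie the pattern and was not tested.

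The third pattern is the low number of genes past the test in days 1 to 3. Fewer arrays would lower the late counts as much, but with 3 of its 4 days the late window still gave at least 4181 genes in the any-arm test, against 49 early. The arms had parted in part by day 1, when the streak median stood at 2.81 above day 0 in FBW, 0.70 in BW, 0.55 in FW and -0.13 in FB. That the arms had parted in fewer genes on day 1 than on days 2 and 3 may account for the low count, since FB, BW and FW had 37, 63 and 32 genes at least 4-fold from FBW on day 1 and 334, 175 and 368 on day 2, and the any-arm count without day 1 was 2044. A biological basis in the timing of the added factors cannot be separated from the day of sampling here.

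Chance naming of the arms within days was tested for the any-arm counts. Of 100 namings drawn within each day 1, the real one, gave as many genes, both in days 1 to 3 (49, highest other 9) and in days 4 to 8 (6639, highest other 3260), so chance naming can be excluded there as far as days are independent. An effect of 1 culture that lasts over days is not excluded. For a pair of arms the swaps within days number 4 early and 8 late, and for day 8 against day 1 the swaps within arms number 8, too few for a share under 0.05. The real late counts and the highest others of these swaps were 6510 and 0 for FB, 6983 and 2 for FW, 3098 and 0 for BW and 6507 and 229 for day 8 against day 1.

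Other splits of the same arrays into groups of the same sizes mix the days (or arms) that the fits keep apart as blocks, so they do not decide on chance, a reading that was made stricter after their counts were seen. In days 4 to 8, 1 of 35 such splits gave as many genes as the real one for FB, FW and BW each, with highest others of 0, 2 and 723. For day 8 against day 1 it was 1 of 35, with 2083 as the highest other, and for the any-arm test of days 4 to 8 it was 1 of 99, with 4860. For the any-arm test of days 1 to 3, 4 of 100 splits gave as many as 49, and the highest other gave 1268 genes. That is several times the real count, but the arms were apart from FBW in more genes on days 2 and 3 than on day 1. A split that mixes days can pick this up, so the count does not show a structure beyond the arms.

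In days 1 to 3 the 10 unrestricted splits of each pair of arms are too few for a share under 0.05. The real counts and the highest others were 28 and 0 for FB (1 split as large), 105 and 0 for FW (1 split) and 1 and 30 for BW (3 splits). For FB against FW the real count was 0 in both windows, so all 10 and all 35 splits gave as many by construction and say nothing about chance. The highest others gave 0 and 1592 genes. The latter came from a split that mixes days, so no conclusion is drawn from it.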

How the results depend on the processing

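FB against FW and its alternatives were chosen after seeing the data. Counts stayed within 1.5 times for FB and FW against FBW in days 4 to 8 and for day 8 against day 1 under each alternative run. The cause was not tested for the changes below, except where fewer days or genes entered. In days 1 to 3 the counts were, for FB (28), FW (105), BW (1) and any arm (49) where moved: quantile normalisation 6, 31, 5 and 18; detection on each array 12, 33, 2 and 25; array weights 3648, 2639, 24 and 2673. The mean of a gene's probes gave 44, 61 and 3 for FB, FW and BW, and each probe by itself 54, 243 and 5. No filter on dim probes gave 189 for FB and 24 for BW, no trend 52 and 3. A fit of only the 2 arms gave 1 for FB and 2 for FW. Without the day block FW had 40, any arm 29 and BW 0 (968 at an unadjusted p under 0.05 in limma).

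Leaving out 1 day gave early ranges of 0 to 2757 for FB, 0 to 2757 for FW, 0 to 350 for BW and 0 to 2044 for any arm. The highest came without day 1. Without day 2 the counts of 0 had 888, 1030, 481 and 562 genes at an unadjusted p under 0.05, and without day 3 FB and FW had 1176 and 1073. In days 4 to 8 the ranges were 4781 to 6061 for FB, 5247 to 6504 for FW, 1166 to 2801 for BW and 4181 to 6068 for any arm, and BW without the day block had 1477. FB against FW in days 4 to 8 went from 0 to 1 with the authors' values, 1 with detection on each array, 91 with array weights and 185 with only the 2 arms. The FBW course on day 8 (1067) gave 366 with quantile normalisation, 679 with detection on both arrays and 3293 at 2-fold. List calls went from 60 to 2 with an estimated correlation. Among the other scalings, quantile normalisation moved the share of higher calls by over 10 points for FW early, from 53 of 105 to 19 of 31, and for BW early, from 1 of 1 to 4 of 5. Other settings moved early shares as well. Detection on each array gave 66.7% for FB (42.9% before) and 60.6% for FW (50.5% before), and no filter on dim probes 39.3% for FW and 33.3% for BW. No trend gave 33.3%, the mean of a gene's probes 66.7%, each probe by itself 80.0%, array weights 70.8% and leaving out day 1 69.4% for BW, and the fit of only the 2 arms 0% for FB and FW. Chip as a block could not be run. Signal near background limits folds of undetected genes to bounds.

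Of the 124 gene comparisons named, 0 reversed their sign under an alternative. For many alternatives this was fixed in advance. Other filters, no trend, no block and a fit of only the arms compared leave the size of a difference unchanged. The setting of each probe by itself used the same probe for these genes. The largest rises and falls had the same sign on each day or arm, so leaving 1 out could not reverse them. A call was lost in 112 of their alternative values, 106 of these in days 1 to 3. With quantile normalisation the early calls lost were ADM, TENT5B, LINGO1, CPM, MSX1, LEF1, CNTFR, WNT8A and CD1D in FB and BNC2, HAND1, MESP1, HAS2 and MSX2 in FW. In days 4 to 8 the calls lost were COL3A1 in FB, ACTA2 in FW, and GABRP and FOXA2 in BW without the day block, and GABRP and MEF2C in BW without day 5. Apart from the estimated correlation, 6 list values lost their call. These were neuroectoderm in BW and smooth muscle, fibroblast and epicardium in FW with quantile normalisation and with the authors' values, caudal HOX and CDX in FW with the authors' values, and endoderm and liver for day 8 against day 1 with quantile normalisation.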

Other observations

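The genes in this paragraph were chosen after their values were seen. From day 4 on, 14 genes were at least 2-fold higher in BW than in each of the other 3 arms on at least 3 days, and 0 were lower in that way. They include FOXA2 (mean log2 signal 9.97 in BW, 8.12 in FBW, 5.82 in FB and 4.95 in FW) and FOXA1 (7.35, 6.14, 5.14 and 4.64), transcription factors of endoderm, and the noncoding LINC00261 (7.61, 5.84, 4.81 and 4.32). CXCR4, a chemokine receptor, had 7.28 in BW and 5.88 in FBW, and CST1 7.51 and 5.68. Also among them were SLCO2A1 (9.16 in BW, 7.32 in FBW), LPL, a lipoprotein lipase (7.29 and 4.83), and the growth factor gene NRG1 (6.80 and 5.10). The same count for FBW was 227 higher and 251 lower, for FB 2 and 0 and for FW 0 and 4.

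Among genes at least 4-fold apart between FB and FW on a late day, those with the largest mean distance were higher in FB. The means are over days 4 to 8. These genes included heart transcripts and were likewise chosen after their values were seen. MYH6 averaged 7.71 in FB and 5.71 in FW, NPPB, a natriuretic peptide gene, 7.94 and 6.16, MYL4 7.47 and 6.14, and MYL7 7.23 and 6.08. The liver transcripts FGA and APOA4 averaged 8.32 and 7.61 in FB and 6.67 and 6.17 in FW. On day 4 MYH6 was lower in FB by -0.17, and on day 5 it was higher by 3.65. No gene passed the test in the fit of all 4 arms, whose smallest adjusted p was 0.0513 in limma.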
